A study of Mus musculus with 5 samples.

How the data were processed

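γH2AX ChIP-seq libraries of primary mouse embryonic fibroblasts with 4 Rb genotypes, 1 library each, and 1 input library were analysed from the files that the authors deposited. Per the labels' protocols, the libraries were made for the Illumina platform and sequenced with paired ends on a HiSeq instrument. Genotypes were taken from the labels, and the input, whose genotype the labels do not give, served as the common reference.

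The authors deposited, for each of the 5 libraries, whole-number read counts for 12 repeat classes, which include lines for tandem repeats and for the unique genome, and for 13 satellite families. The family counts add up to the satellite class in each library. Bowtie 1.0, MACS 1.4.2 and the genome build mm9 are named per the submitters' processing notes, which give them no role or order. How a read that fits several copies of a repeat was counted, the aligner settings and whether duplicate reads were removed are not given in the sources used here. The choice enters both the level of a repeat class and, through the total, its ratio between libraries, and its effect was not examined here.

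For each ChIP library the authors deposited a list of peaks with a score for each peak. The lists were assigned to genotypes by the sample each was deposited with, although the sample number that each list carries is 1 higher than the one the labels give that sample, and all peak results rest on this assignment. The peak names in the lists are those that MACS writes, and the scores run from 50 to 3100. The score is read here as minus 10 times the base-10 logarithm of the peak's p-value, as MACS of that version writes it, although no file header says so. The control library, the p threshold and the read end used for calling are not given in the sources used here, and lists were called per library, not on pooled samples. A p-based score depends on the depth and background of its library, so scores were used to describe and rank peaks within a list, and where scores of several libraries are given for 1 region they are not on one scale.

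Each class or family count was divided by the library's total over all classes, and shares were given exact (Clopper-Pearson) 95% binomial intervals. Ratios to the input or to the Rb+/+ library were given 95% counting intervals on the log ratio. The same input library entered all 4 ratios to input and the same Rb+/+ library all 3 ratios to Rb+/+, so the ratios share the chance error of that library. Reads without molecular identifiers are not independent molecules, and the intervals cover counting error only. A count of 0 was read as allowing up to 3 counts, a share of at most 1.68e-05% to 2.18e-05% of a library's total, and no ratio was given for families with at most 3 counts in each library. With 1 library per genotype no test between genotypes was run.

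Peaks were compared by overlap of at least 1 bp, and overlapping peaks of the 4 lists were merged into regions. The level of chance was taken from 100 random placements (seed 1) of each peak on its own chromosome, between the lowest and highest peak coordinate there. Shares of peaks per chromosome and in the first 10 Mb were given exact binomial intervals. Coordinates are those of the deposited lists, written from 1. The items named in the text were fixed before the data were examined as every repeat class and satellite family, the 5 highest-scoring peaks of each library, the 10 regions found in all 4 libraries with the highest lowest score, the 10 highest of the regions found in the mutants without Rb+/+, of which there were 0, and the 10 highest of the regions found in Rb+/+ alone. Other positions named in the text were chosen after their values were seen.

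The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated peak lists modelled on Rb+/+ and RbΔL/+, 200 of 200 planted overlaps were recovered, as by bedtools 2.31.1. On simulated counts modelled on Rb+/+ against the input, the 95% intervals on ratios covered the known value in 94.6% to 95.7% of 1000 draws.

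Alternatives set before the data were examined were other denominators for the shares, the Rb+/+ library in place of the input, scaling to a median class ratio of 1, a peak score of at least 100, merging of peaks within 1000 bp, overlap of 50% both ways or within 1000 bp, equal numbers of top peaks, numbered autosomes and X only, and 5 or 20 Mb in place of 10 Mb. Further alternatives for the satellite ratios and for the X share were added after the data were seen. Comparisons of peaks with genes and with fixed gene lists had been planned but were left out, since gene annotation of the build mm9 was not used here, and the Rb locus itself was not examined.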

Results

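γH2AX, the form of the histone variant H2AX that is phosphorylated around damaged DNA and stalled replication forks, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in primary mouse embryonic fibroblasts that were proliferating at passage 4. The cells carried 1 of 4 Rb genotypes. Rb+/+ cells have both copies of the gene for the retinoblastoma protein, a repressor of E2F transcription factors, and Rb-/- cells lack it. RbΔL/+ and RbΔL/ΔL cells carry 1 or both copies of the ΔL allele, which is altered in the cleft that binds proteins with an LXCXE motif. There was 1 ChIP library per genotype and 1 input library of DNA without immunoprecipitation, whose genotype the labels do not give. The read counts totalled 17180437 in the input, 17896985 in Rb+/+, 13731924 in RbΔL/+, 16061083 in RbΔL/ΔL and 16703500 in Rb-/-. With 1 library per genotype no difference between genotypes has a replicate check, so the values below describe these libraries, and their 95% intervals cover counting error only.

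The title of the series ties an RB-E2F1-Condensin II complex to replication stress, and the repeat counts address where in the repetitive part of the genome γH2AX lay in each genotype. Satellite repeats made up a smaller share of the counts in every ChIP library than in the input, and the smallest share was in Rb+/+. The satellite share was 3.95% of counts in the input, 2.71% in Rb+/+, 3.13% in RbΔL/+, 3.18% in RbΔL/ΔL and 3.15% in Rb-/-. Relative to the input, satellites stood at 0.686 (0.683 to 0.688) in Rb+/+, 0.792 (0.789 to 0.795) in RbΔL/+, 0.805 (0.802 to 0.807) in RbΔL/ΔL and 0.797 (0.794 to 0.7998) in Rb-/-. Set against the Rb+/+ library, the satellite share was 1.16 times as large in RbΔL/+ (1.15 to 1.16), 1.17 times in RbΔL/ΔL (1.17 to 1.18) and 1.16 times in Rb-/- (1.16 to 1.17). The 3 mutant libraries lay close together, the highest of them at 1.02 times the lowest. All 3 ratios rest on the same Rb+/+ library, and in the absence of any difference between genotypes that library would be the lowest of the 4 in 25% of cases. Scaling each library so that its median repeat class ratio to input was 1, which shifted RbΔL/+ by 0.16 on the log2 scale, left almost no difference between RbΔL/+ and Rb+/+ (1.004 times), while RbΔL/ΔL and Rb-/- stood at 1.16 and 1.12 times Rb+/+. This scaling weighs large and small classes alike. In RbΔL/+ it placed the unique genome, 89.0% of the counts, at 0.897 times the input. With the median class ratio to Rb+/+ set to 1 instead, the 3 mutants stood at 1.04, 1.17 and 1.13.

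The major satellite GSAT_MM, the main repeat of mouse pericentromeres, held most of the satellite counts, from 91.6% of them in Rb+/+ to 94.3% in the input. Its share of all counts was 0.666 times the input (0.663 to 0.668) in Rb+/+, 0.781 (0.778 to 0.784) in RbΔL/+, 0.7997 (0.797 to 0.803) in RbΔL/ΔL and 0.776 (0.773 to 0.779) in Rb-/-. Against Rb+/+, GSAT_MM was higher by factors of 1.17 in RbΔL/+, 1.201 in RbΔL/ΔL and 1.17 in Rb-/-. SATMIN, the minor satellite of the centromere, was at 0.879 (0.854 to 0.906) of the input in Rb+/+, 0.972 (0.942 to 1.00) in RbΔL/+, 0.960 (0.931 to 0.989) in RbΔL/ΔL and 1.13 (1.10 to 1.16) in Rb-/-. Relative to Rb+/+, SATMIN was therefore also higher in the 3 mutant libraries, at 1.11, 1.09 and 1.29 in the same order. As a share of satellite counts alone, SATMIN lay above the input in all 4 libraries, at 1.28 times in Rb+/+, 1.23 in RbΔL/+, 1.19 in RbΔL/ΔL and 1.42 in Rb-/-, so that on this scale RbΔL/+ and RbΔL/ΔL were below Rb+/+.

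**Figure D1:**
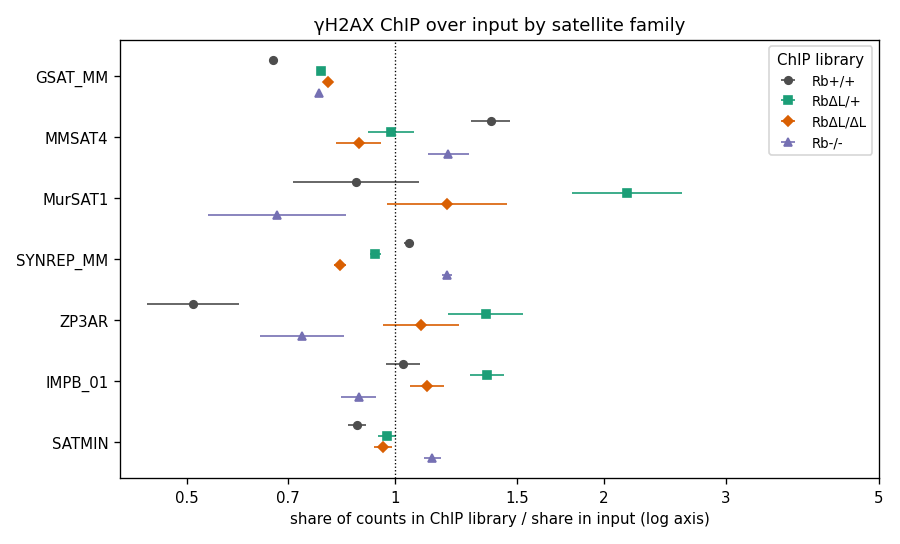
Share of each satellite family among all counts of a ChIP library divided by its share in the input, on a log axis, for the 7 families with more than 3 counts; points are the 4 libraries and bars are 95% counting intervals. GSAT_MM lies left of 1 in every library, from 0.666 in Rb+/+ to 0.7997 in RbΔL/ΔL, while MurSAT1 spreads from 0.674 in Rb-/- to 2.16 in RbΔL/+.

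The smaller satellite families did not share one order of genotypes. MMSAT4 was higher in Rb+/+ (1.37 times the input, 1.29 to 1.47) and Rb-/- (1.19, 1.11 to 1.28) than in RbΔL/+ (0.985, 0.914 to 1.06) and RbΔL/ΔL (0.884, 0.821 to 0.953). SYNREP_MM had the same split, at 1.05 and 1.19 in Rb+/+ and Rb-/- and at 0.935 and 0.831 in RbΔL/+ and RbΔL/ΔL. MurSAT1, ZP3AR and IMPB_01 had the opposite one and were highest in RbΔL/+. MurSAT1 stood at 2.16 (1.80 to 2.59) in RbΔL/+, 1.19 (0.972 to 1.45) in RbΔL/ΔL, 0.876 (0.710 to 1.08) in Rb+/+ and 0.674 (0.536 to 0.849) in Rb-/-. For ZP3AR the ratios were 1.35 in RbΔL/+, 1.09 in RbΔL/ΔL, 0.732 in Rb-/- and 0.509 in Rb+/+, and for IMPB_01 they were 1.36, 1.11, 0.884 and 1.03. MurSAT1 rests on 120 to 316 counts per library. As shares of satellite counts alone, SYNREP_MM in RbΔL/+ and RbΔL/ΔL, MMSAT4 in RbΔL/ΔL and IMPB_01 in Rb-/- lay above the input, at 1.18, 1.03, 1.10 and 1.11 times. So did MMSAT4 in RbΔL/+ (1.24) and MurSAT1 in Rb+/+ (1.28), whose intervals on the first scale included 1. On the satellite scale IMPB_01 was at 1.496 in Rb+/+ and 1.38 in RbΔL/ΔL, so its split no longer held. The 6 remaining families, SQR1_MM, SQR2_MM, SQR4_MM, SVA2, TAR1 and ZP3AR_MM, had at most 2 counts in any library, and no ratio is given for them.

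Among the other repeat classes, the Pseudogene class stood furthest above the input. It was 6.11 times the input (5.83 to 6.41) in Rb+/+, 5.27 times (5.02 to 5.54) in RbΔL/+, 3.64 times (3.46 to 3.83) in Rb-/- and 1.49 times (1.403 to 1.58) in RbΔL/ΔL, on 12486, 8259, 6936 and 2726 counts. The order of the 4 libraries for Pseudogene was thus the reverse of that for satellites at its ends, with Rb+/+ highest and RbΔL/ΔL lowest. LTR retrotransposons in Rb-/- were at 0.407 times the input (0.358 to 0.463, 325 counts), against 0.963 in Rb+/+, 1.16 in RbΔL/+ and 0.967 in RbΔL/ΔL. LINEs, the long interspersed elements, were highest in Rb-/- at 1.203 (1.197 to 1.208), followed by 1.09 in Rb+/+, 1.04 in RbΔL/+ and 1.01 in RbΔL/ΔL, and the RbΔL/+ value lay below 1, at 0.931, when its median class ratio was set to 1. Endogenous retroviruses were highest in RbΔL/+ at 1.13 (1.13 to 1.14) and were at 1.08 in Rb-/-, 1.03 in Rb+/+ and 1.01 in RbΔL/ΔL.

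SINEs, simple repeats and DNA transposons were also highest in RbΔL/+. SINEs stood at 1.11 there, 1.01 in Rb-/-, 0.980 in Rb+/+ and 0.929 in RbΔL/ΔL, and with the median class ratio of each library set to 1 the RbΔL/+ value became 0.989, below Rb+/+ (1.01) and Rb-/- (1.00). Simple repeats stood at 1.25 in RbΔL/+, 1.06 in Rb+/+, 0.970 in Rb-/- and 0.9004 in RbΔL/ΔL. DNA transposons ranged only from 0.941 in Rb-/- to 1.02 in RbΔL/+. With the median class ratio of each library set to 1, RbΔL/+ was instead the lowest of the 4 for DNA transposons (0.910) and endogenous retroviruses (1.01). Other transposable elements were lowest in Rb+/+ at 0.874 and were 1.17 in RbΔL/+, 1.00 in RbΔL/ΔL and 1.18 in Rb-/-. The class that the authors named other had 0.857 in Rb+/+, 1.14 in RbΔL/+, 0.986 in RbΔL/ΔL and 1.397 in Rb-/-. Tandem repeats ran from 0.942 in Rb+/+ to 1.01 in RbΔL/+, and the unique genome, with 88.7% to 89.8% of counts, stayed between 1.00 and 1.01, although both were at 0.90 and 0.897 in RbΔL/+ with the median class ratio set to 1. RbΔL/ΔL was the library nearest to the input, with 8 of 12 classes within 5% of it against 4 of 12 in each other ChIP library. Across the 12 classes, Rb+/+ was the lowest or the highest of the 4 ChIP libraries for 6, where a chance order gives 50% for any single class. The classes share 1 total and are not independent, so this count is not a test of chance.

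**Figure D2:**
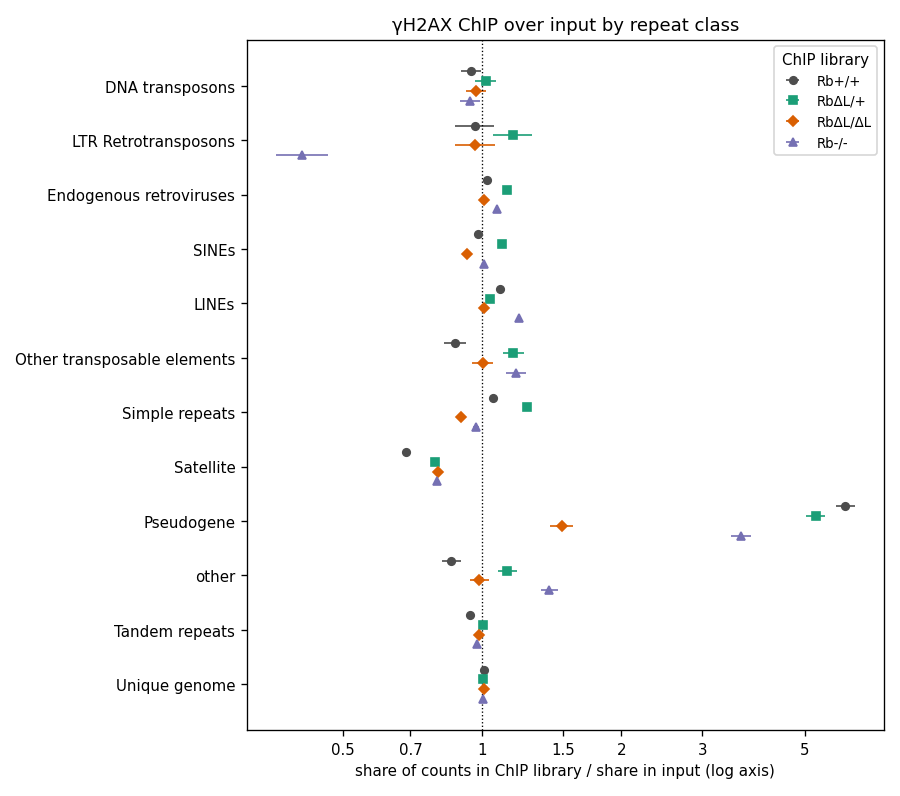
Share of each repeat class among all counts of a ChIP library divided by its share in the input, on a log axis; points are the 4 libraries and bars are 95% counting intervals. Satellites lie left of 1 in all 4 libraries with Rb+/+ lowest at 0.686, and the Pseudogene class lies right of 1 with Rb+/+ highest at 6.11.

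Peaks of γH2AX were listed by the authors for each ChIP library on its own, and their number differed between the libraries. Rb+/+ had 3857 peaks and RbΔL/+ had 3789, whereas RbΔL/ΔL had 1976 and Rb-/- had 1632. The peaks covered 1.53 Mb in Rb+/+, 1.52 Mb in RbΔL/+, 0.640 Mb in RbΔL/ΔL and 0.597 Mb in Rb-/-, with median widths of 390, 408, 321 and 341 bp. Each peak carries a score from the authors, larger for a smaller p-value. It is used here to describe and rank peaks within a list and, with a limit of 100, to filter the lists. A score of at least 100 was reached by 849 peaks in Rb+/+ (22.0%, 20.7 to 23.4), 165 in RbΔL/+ (4.35%, 3.73 to 5.05), 19 in RbΔL/ΔL (0.962%, 0.580 to 1.498) and 751 in Rb-/- (46.0%, 43.6 to 48.5). With that limit Rb-/- had more peaks than RbΔL/+ and RbΔL/ΔL, where it had fewer than either in the full lists. The score depends on a library's depth and background, so neither count is a measure of how much γH2AX a genotype had. For the same reason a limit of 100 need not be equally strict in each library.

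Nearly every peak was found in a single library. The 4 lists merged into 11151 regions, of which 11088 (99.4%) held peaks of 1 library, 41 of 2 libraries, 10 of 3 and 12 of all 4. Of the peaks in RbΔL/+, 37 (0.977%, 0.688 to 1.34) overlapped a peak of Rb+/+ by at least 1 bp, as did 18 (0.911%, 0.541 to 1.44) in RbΔL/ΔL and 28 (1.72%, 1.14 to 2.47) in Rb-/-. Random placement of peaks on the same chromosomes gave means of 4.05, 2.12 and 1.73 overlaps and at most 8, 7 and 5 in 100 placements. Overlap was concentrated at the top of the lists, where 10 of the 10 highest-scoring peaks in Rb+/+, RbΔL/+ and Rb-/- and 7 of 10 in RbΔL/ΔL were also found in another library. Below rank 200 this applied to 0.602% of peaks in Rb+/+, 0.613% in RbΔL/+, 0.901% in RbΔL/ΔL and 0.978% in Rb-/-. No region held a peak in all 3 mutant libraries without one in Rb+/+. None of the 100 random placements gave such a region either, so this absence cannot be told apart from chance.

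The 12 regions with a peak in all 4 libraries lay on chromosomes 2, 6, 9, 12 and 17, and none of the 100 random placements gave a region of this kind. Those placements are uniform and take no account of repeated or hard-to-map DNA. Input reads at these regions were not examined. Shared sites of γH2AX therefore cannot be told apart from places where reads pile up in any library. The highest-scoring peak of every library was on chromosome 2 at 98506246 to 98507611 (mm9), with scores of 3100 in Rb+/+, RbΔL/+ and Rb-/- and 1372.33 in RbΔL/ΔL. The identical 3100 may be an upper limit of the score, so it does not show that these libraries were equal there. A neighbouring region on chromosome 2, at 98502258 to 98503270, had scores of 1955.59 in Rb+/+, 2135.28 in RbΔL/+, 605.25 in RbΔL/ΔL and 2387.72 in Rb-/-, and a smaller one lay between them at 98505037 to 98505539. On chromosome 9, 5 of the 6 shared regions fell within the first 10 Mb, at the centromeric end, and the strongest of these, at 3023060 to 3024847, ranked 5 in Rb+/+, 4 in RbΔL/+ and 4 in Rb-/- but was not among the 10 highest in RbΔL/ΔL (score 144.92). The other 4 at that end were at 2999906 to 3001810, 3001942 to 3002997, 3006540 to 3007167 and 3024923 to 3026219. The other shared region of chromosome 9 was at 35112647 to 35113256, and that of chromosome 6 was at 103598949 to 103599514. Gene annotation of this genome build was not used here, so these regions are named by position.

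**Figure D3:**
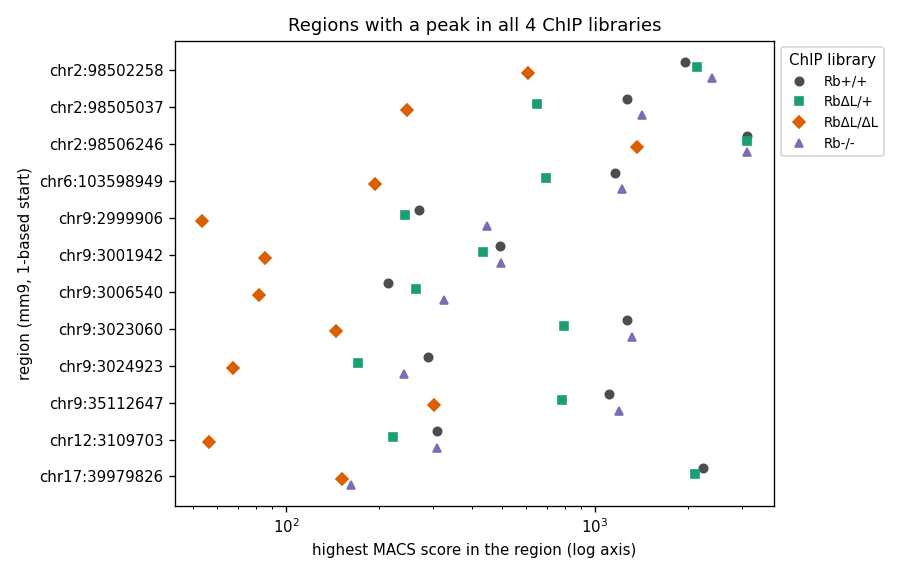
Highest peak score listed by the authors in each of the 12 regions with a peak in all 4 ChIP libraries, on a log axis, with regions named by their mm9 start; each point is 1 library, and scores of different libraries are not on one scale. Within each library the region on chromosome 2 at 98506246 has the highest score, 3100 in Rb+/+, RbΔL/+ and Rb-/- and 1372.33 in RbΔL/ΔL. The identical 3100 may be an upper limit of the score.

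A region of 6116 bp on chromosome 17, at 39979826 to 39985941, differed in rank between the lists. It held the peak of rank 2 in Rb+/+ (score 2233.31) and of rank 3 in RbΔL/+ (score 2107.06), but was not among the 10 highest in RbΔL/ΔL (151.91) or Rb-/- (161.93). In all 4 libraries most of the region was covered by peaks, 6116 bp in Rb+/+, 5882 bp in RbΔL/+, 5256 bp in RbΔL/ΔL and 5203 bp in Rb-/-. On chromosome 11, 3 adjoining peaks between 74578883 and 74583510, a stretch of 4628 bp, ranked 2, 3 and 5 in RbΔL/ΔL with scores of 729.91, 626.6 and 456.21. None of the other libraries had a peak in that stretch. Peaks of Rb+/+ alone numbered 3813 regions, and the highest-scoring of them were narrow and modest in score. They were led by chromosome 7 at 62458709 to 62458920 (score 252.28), chromosome 2 at 33493204 to 33493411 (237.98) and 4 regions with a score of 230.64, on chromosome 1 at 96796917 to 96797130 and on chromosome 10 at 28377405 to 28377622, 87584328 to 87584555 and 88810614 to 88810826. The next 4, with a score of 209.32, were on chromosome 1 at 101913733, chromosome 11 at 48022804 and 89738824, and chromosome 12 at 114325607.

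Along the chromosomes, the X and Y set RbΔL/+ apart from the other libraries. Chromosome X held 2.11% (1.68 to 2.62) of peaks in RbΔL/+, against 6.43% (5.68 to 7.25) in Rb+/+, 5.16% (4.23 to 6.23) in RbΔL/ΔL and 5.27% (4.24 to 6.47) in Rb-/-. Among peaks with a score of at least 100 the X share was instead lowest in RbΔL/ΔL, at 0% of only 19 peaks, against 2.42% in RbΔL/+. The Y chromosome held 18 peaks in RbΔL/+, between 2779645 and 2892245, and 0 in the other 3 lists. The first 10 Mb of the chromosomes, where mouse centromeres lie, held 5.29% (4.60 to 6.04) of peaks in Rb+/+, 6.49% (5.73 to 7.32) in RbΔL/+, 6.28% (5.25 to 7.44) in RbΔL/ΔL and 5.76% (4.68 to 7.003) in Rb-/-. At this limit the share was highest in RbΔL/+, and the difference itself was not tested. All 18 Y peaks of RbΔL/+ lie in this stretch and are counted in its share. RbΔL/+ had 246 of 3789 peaks there, and without the Y peaks its share would fall below that of RbΔL/ΔL (124 of 1976). Its place as the highest at this limit therefore rests on them. Within the first 20 Mb the share was highest in Rb-/- at 13.3%, with RbΔL/+ (12.4%) close to Rb+/+ (12.3%). Among peaks with a score of at least 100, RbΔL/+ had 11.5% in the first 10 Mb, on 165 such peaks, of which at least 1 lies on Y. The share was 5.18% in Rb+/+, 5.26% in RbΔL/ΔL, which has only 19 such peaks, and 5.59% in Rb-/-.

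**Figure D4:**
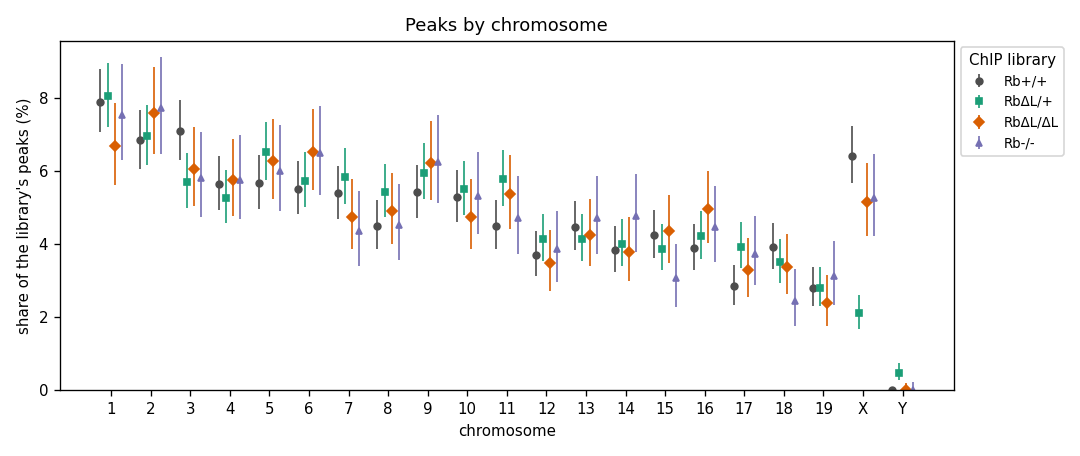
Percentage of each ChIP library's peaks on each chromosome; points are the 4 libraries and bars are exact 95% binomial intervals. On X, RbΔL/+ is at 2.11% and the other libraries are between 5.16% and 6.43%, and on Y only RbΔL/+ has peaks.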

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

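The tests of background and of the order of libraries in this part were chosen only after the satellite values were seen.

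Several repeat classes and families lay below the input in one genotype and above it in another, in each case by more than counting error. The differences between genotypes were not tested, since each rests on 1 library per genotype. LTR retrotransposons ran from 0.407 times the input in Rb-/- to 1.16 in RbΔL/+, SINEs from 0.929 in RbΔL/ΔL to 1.11 in RbΔL/+, and simple repeats from 0.9004 in RbΔL/ΔL to 1.25 in RbΔL/+. Other transposable elements ran from 0.874 in Rb+/+ to 1.18 in Rb-/-, the class named other from 0.857 in Rb+/+ to 1.397 in Rb-/-, and tandem repeats from 0.942 in Rb+/+ to 1.01 in RbΔL/+. With the median class ratio set to 1, RbΔL/+ lay below the input for SINEs (0.989) and tandem repeats (0.90) and was at 1.04 for LTR retrotransposons. Among satellite families, MMSAT4 ran from 0.884 in RbΔL/ΔL to 1.37 in Rb+/+, and SYNREP_MM from 0.831 in RbΔL/ΔL to 1.19 in Rb-/-. MurSAT1 ran from 0.674 in Rb-/- to 2.16 in RbΔL/+, ZP3AR from 0.509 in Rb+/+ to 1.35 in RbΔL/+, IMPB_01 from 0.884 in Rb-/- to 1.36 in RbΔL/+, and SATMIN from 0.879 in Rb+/+ to 1.13 in Rb-/-. As shares of satellite counts alone, the low ends of MMSAT4, SYNREP_MM, IMPB_01 and SATMIN lay above the input, at 1.10, 1.03, 1.11 and 1.28.

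The satellite share was higher than in Rb+/+ in the 3 mutant libraries, by factors of 1.16 to 1.17, although RbΔL/+ came to 1.004 with the median class ratio to input set to 1. If more input-like background were the only difference from Rb+/+, every other class would lie between its Rb+/+ ratio to input and 1, and 7 of 11 lay outside that range in RbΔL/+, 2 of 11 in RbΔL/ΔL and 6 of 11 in Rb-/-. These margins hold counting error but not variation between libraries, which 1 library per genotype cannot measure, so background cannot be told apart from other causes, whether counted by library or, as was done first, over the 3 mutants together (15 of 33). Background acting on satellites alone also stays open. The input-like share that satellites would need exceeded that of the Pseudogene class in 1 of 3 mutants, but the Pseudogene class need not share such a background. Among the families, GSAT_MM lay between its Rb+/+ ratio and 1 in the 3 mutants. SYNREP_MM lay outside that range, at 0.935 in RbΔL/+, 0.831 in RbΔL/ΔL and 1.19 in Rb-/- against 1.05 in Rb+/+. Other families went both ways. These values too carry counting error only, so they cannot decide. A chance order of the 4 libraries cannot be told apart either, since 1 library per genotype gives no measure of it. Rb+/+ was lowest or highest for 6 of 12 classes, but the classes share 1 total and are not independent. That count therefore says nothing of the order for satellites, and the genotype itself remains open and untested.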

How the results depend on the processing

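The values without the unique genome for satellite ratios, the satellite ratios to Rb+/+ under both median scalings, and the X shares by score were chosen only after the data were seen. Of 504 alternative values, 258 stayed within the interval or the factor of 1.5 set for them and 32 were ratios whose interval lay on one side of 1 before and on the other side after. The rest moved without such a crossing. Leaving out the unique genome raises every other class share by design, and a ratio to Rb+/+ is another quantity than a ratio to input. These numbers are therefore not a rate of robustness. No paired analysis was possible because each genotype has 1 library. No ratio was given for 6 satellite families with at most 2 counts in each library, and RbΔL/ΔL has only 19 peaks with a score of at least 100. Comparisons with genes were not run, a total without satellites gives no satellite share, and a satellite total without GSAT_MM gives no GSAT_MM value.

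The higher satellite share of RbΔL/ΔL and Rb-/- kept its direction under the scalings tried, and that of RbΔL/+ nearly vanished under 1 of them. Without the unique genome the ratios to Rb+/+ were 1.07 in RbΔL/+, 1.14 in RbΔL/ΔL and 1.07 in Rb-/-, and with a median class ratio to Rb+/+ of 1 they were 1.04 in RbΔL/+ and 1.13 in Rb-/-. With the median class ratio to input at 1 in both libraries they were 1.004 in RbΔL/+, 1.16 in RbΔL/ΔL and 1.12 in Rb-/-. The larger drop in RbΔL/+ comes mainly from its median class ratio of 1.12 to both references. Without the unique genome the satellite shares were 35.1% in the input, 26.6% in Rb+/+, 28.5% in RbΔL/+, 30.5% in RbΔL/ΔL and 28.6% in Rb-/-, and the ratios to input were 0.759, 0.813, 0.868 and 0.816 in the 4 ChIP libraries in that order. With a median class ratio of 1 the satellite ratios to input were 0.705, 0.708, 0.816 and 0.792.

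Several ratios crossed 1 because the reference changed from the input to Rb+/+. In RbΔL/+, RbΔL/ΔL and Rb-/-, satellites then stood at 1.16, 1.17 and 1.16, GSAT_MM at 1.17, 1.201 and 1.17, Pseudogene at 0.862, 0.243 and 0.595, and the unique genome at 0.991, 0.997 and 0.991. LINEs stood at 0.952 in RbΔL/+ and 0.922 in RbΔL/ΔL, tandem repeats at 1.05 in RbΔL/ΔL and 1.04 in Rb-/-, and endogenous retroviruses at 0.982 and SATMIN at 1.09 in RbΔL/ΔL. MMSAT4 stood at 0.869 and ZP3AR at 1.44 in Rb-/-. With a median class ratio of 1, RbΔL/+ had 0.989 for SINEs, 0.931 for LINEs, 0.90 for tandem repeats and 0.897 for the unique genome, and Rb-/- had 0.997 for the unique genome.

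As shares of satellite counts, GSAT_MM was at 0.971, 0.986, 0.994 and 0.973 times the input in Rb+/+, RbΔL/+, RbΔL/ΔL and Rb-/-. On that scale MMSAT4 in RbΔL/ΔL was at 1.10, SYNREP_MM at 1.18 in RbΔL/+ and 1.03 in RbΔL/ΔL, IMPB_01 in Rb-/- at 1.11, and SATMIN at 1.28 in Rb+/+ and 1.19 in RbΔL/ΔL. The satellite total itself, low in GSAT_MM in every ChIP library, accounts for these except SATMIN in RbΔL/ΔL. Without GSAT_MM in the total, SATMIN in RbΔL/ΔL was still at 1.08, and the cause was not tested.

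With a score of at least 100, the 4 ChIP libraries kept 849, 165, 19 and 751 peaks over 227166, 63878, 15654 and 204806 bp, with median widths of 237, 221, 480 and 238 bp. The percentages shared with Rb+/+ became 11.5% in RbΔL/+, 36.8% in RbΔL/ΔL and 2.66% in Rb-/-, and 7 regions were found in all 4 libraries. X held 7.42% of such peaks in Rb+/+, 2.42% in RbΔL/+, 0% in RbΔL/ΔL and 4.26% in Rb-/-, so at this limit RbΔL/+ was not the lowest. The value of RbΔL/ΔL rests on only 19 peaks, too few to rank it, and RbΔL/+ stayed below Rb+/+ and Rb-/-. In the first 10 Mb lay 11.5% of such peaks in RbΔL/+. With the 1632 top peaks of each library, 1.78% of those in RbΔL/+ were shared with Rb+/+. Within the first 5 Mb lay 1.76%, 2.64%, 1.77% and 1.90% of peaks, and within 20 Mb 12.3%, 12.4%, 12.7% and 13.3%. Both RbΔL/+ values include its 18 Y peaks, and without them RbΔL/+ would still be highest within 5 Mb. The smaller peak numbers and lengths and the shares within 5 and 20 Mb follow from those limits themselves. Overlap between libraries lay mostly at the top of the lists, and limits on score or number keep those peaks, which bears on the higher percentages shared. The cause of the other changes in this paragraph was not tested.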

Other observations

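The tests in this part of random noise, of reads per peak, of sex and of read totals were chosen only after the peak lists were seen, as were the positions named here.

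RbΔL/+ and RbΔL/ΔL, the libraries that carry the ΔL allele, shared 16 regions that had no peak in Rb+/+ or Rb-/-, against a mean of 1.97 and at most 6 in 100 random placements. Rb+/+ and RbΔL/+ had 14 regions to themselves (mean 4.61, at most 10), and the other 4 pairs had 1 to 5, within the range of their random placements. The strongest region of RbΔL/+ and RbΔL/ΔL alone was on chromosome 11 at 87236216 to 87236975, with scores of 309.45 and 281.76, and a neighbour lay at 87240042 to 87240865. Another pair lay on chromosome 9, at 65044130 to 65044683 and 65049254 to 65049799. Of the 10 regions found in 3 libraries, 9 lacked a peak in RbΔL/ΔL. The RbΔL/+ and RbΔL/ΔL libraries also had the smallest shares of peaks with a score of at least 100. These were 4.35% and 0.962%, against 22.0% in Rb+/+ and 46.0% in Rb-/-. With 1 library per genotype the allele cannot be told apart from such differences between libraries, and the cause of the shared regions was not tested. Uniform random placement also takes no account of regions that lie close together.

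Of the 11151 peak regions, 99.4% held peaks of a single library. Noise spread at random along the chromosomes as the source of peaks below rank 200 cannot be told apart from weak shared sites. Of 6 pairs of libraries, 2 overlapped more than in any of 100 random placements (7 against at most 5, both for Rb+/+ with Rb-/- and for RbΔL/+ with RbΔL/ΔL). The other pairs lay within the range of their placements. All 6 lay above the mean of their placements, from 1 against 0.54 for RbΔL/ΔL with Rb-/- to 9 against 4.14 for Rb+/+ with RbΔL/+. Peaks that rest on a few reads are a candidate explanation in Rb+/+ and Rb-/-. There the 4 commonest scores, held by 32.9% and 36.2% of peaks, lay within 0.0102 of a Poisson ladder. That ladder is the scores that at least 5, 6, 7 and 8 reads give under 1 background rate, fitted at 0.0960 and 0.0581. The 1000 uniform random sets of 4 scores came no closer than 0.334. Scores from Poisson p-values of whole read numbers lie on such a ladder by construction where peaks share a background rate. The random sets are therefore no test of the explanation. Only rates of at most 1 were tried, which itself limits the fit to few reads. In RbΔL/ΔL the gap was 3.32, no closer than random sets. Its 4 commonest scores held only 6.38% of peaks and were best matched by 7, 7, 7 and 8 reads, which are not consecutive. The test therefore cannot decide whether peaks of RbΔL/ΔL rest on a few reads. The gap in RbΔL/+, on 14.7% of peaks, was 0.230. It is over the tolerance of 0.05 but closer than the random sets, so RbΔL/+ stays undecided too. Sites of γH2AX that differ by genotype remain open and untested.

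RbΔL/+ had few X peaks and was the only library with Y peaks, 18 of them. The sex of the cells may differ, but it cannot be told apart from other causes with these lists, because the X share in RbΔL/+, at 0.376 times the mean of the other 3 libraries and the lowest of 20 chromosomes, is the observation itself and not a separate test. The lower read total of RbΔL/+ as the cause is argued against by its autosomal peaks, which were 1.02 times as many as in Rb+/+ (3691 against 3609). The labels used here give no sex, and if male cells were compared with female cells then sex would differ between the RbΔL/+ library and the others along with genotype. The genotype as a cause was not tested.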
